A study of Mus musculus with 20 samples.

How the data were processed

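Small RNA was measured in 20 mouse placentas collected with the decidua, the maternal lining, left in place. Per the labels' protocols, C57BL/6 dams ate freely from embryonic day 1 to 8.5, after which control dams continued to do so and dams of the growth-restricted group (IUGR, intrauterine growth restriction) received a diet with 50% fewer calories, about 1.5 to 2.0 g of food per day, until harvest. The labels' protocols also state that libraries were made from 1 µg of total RNA with the TruSeq Small RNA kit and sequenced as single-end reads of 50 bp on a HiSeq instrument.

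The authors deposited 1 table of raw counts per miRNA sequence and library, as the column names state. Larger counts were written as text with commas between groups of digits, which were removed before use, and every value was then a whole number. The build was mm39, per the submitters' processing notes, and the aligner and the miRNA caller are not given in the sources used here. The table held 1546 sequences, of which 1021 were named for known mouse miRNAs, 270 for miRNAs of other species and 255 as predicted. In 31 entries the sequence repeated that of another entry, and 335 entries, 22 of the 694 tested over all libraries, had the same counts as another entry in every library. The sequences of entries with equal counts were not compared, and entries with few counts can share them without being alike. Reads of near-identical miRNAs cannot be told apart, so members of multicopy families such as miR-466, miR-467 and miR-669 are uncertain as single miRNAs. Listed names carry suffixes for end variants and single mismatches, which are left out of the text.

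The total count per placenta ranged from 2115235 to 8744369, and no molecular identifiers were recorded, so counts include PCR copies. Samples were grouped by the treatment label into 10 control and 10 IUGR placentas and numbered in accession order within each group, so equal numbers pair nothing. Sample names follow 2 patterns, a number followed by F (F-suffix) or the letter C or I followed by a number (C/I-infix), each with 5 control and 5 IUGR placentas. The labels do not say what the patterns mean, so they were treated as a possible batch, and the diet effect was tested over all 20 placentas, within each name series and as the difference between the series. Within the 4 group-by-series cells, the 40 pairs of libraries differed by at least 23.1 times the sampling variance of counts (chi-square per degree of freedom), more than counting error alone would give. Pairs across cells were not compared.

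The count-based quasi-likelihood and Wald tests planned for raw counts were not run. The stored table did not read as plain numbers and its values were therefore recorded under another unit than counts, to which those tests were limited, so limma on log2 values took their place. The values with commas removed would have allowed them. Counts per 1000000 counts (CPM) were computed with library totals scaled by trimmed means of M values (TMM, trims of 0.3 and 0.05), and a prior count of 2 scaled to depth was added before taking log2. A miRNA was tested where it reached the CPM equal to 10 counts at the median total (1.92 CPM over all 20 placentas) in at least as many libraries as the smaller group holds, with at least 15 counts in all. This kept 694 miRNAs over all 20 placentas, 715 in the F-suffix and 651 in the C/I-infix placentas. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust set to true, statmod 1.5.0), with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. Fold changes of miRNAs with few counts are understated by the prior count.

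Lists of miRNAs by genomic cluster, family, topic and cell type were fixed by name before the data were examined. The alternatives and the rule for which miRNAs are named were fixed then too. So were the tests, except that limma replaced the count-based tests only after the table had been opened. The lists were the imprinted Dlk1-Dio3 cluster, the Sfmbt2 cluster families, miR-17/92 and paralogs, miR-322/miR-503, miR-290/miR-295, the H19 and Igf2 miRNAs, and the let-7, miR-29, miR-30, miR-15/16, miR-23/27/24, miR-181 and miR-34 families. Topic lists covered hypoxia, nutrient and lipid metabolism, and miRNAs often named in human fetal growth restriction and pre-eclampsia. Marker lists covered erythroid cells, leukocytes, endothelium, smooth muscle and pericytes, fibroblasts and stroma, epithelium, the miR-183/miR-96/miR-182 cluster, striated muscle, liver and neurons. Marker miRNAs are enriched in a lineage and not exclusive to it, and 35 of the 41 miRNAs of the growth-restriction list and 11 of the 14 of the hypoxia list also belong to another list. Lists with at least 3 tested members were compared with all other miRNAs by camera with a preset correlation of 0.01. Camera with an estimated correlation, and fry, which asks whether the members of a list move one way on balance, were run beside it. The share of a library's counts held by each list and the library totals were compared by two-sided permutation tests, with 100000 resamples over all 20 placentas and exact enumeration of the 252 assignments within a series.

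Named in the text are the passing miRNAs of the main comparison with a mean of at least 10 CPM, up to 12 per direction by size of change. Where fewer passed, the list was filled to 12 with those of smallest p, given as values. Added to these are up to 4 passing members of each list or else its most abundant member, 14 miRNAs fixed in advance, the 5 most abundant, and the 5 with the smallest p in each direction within a series and for the difference between series. Other members of the lists that are named within the C/I-infix placentas were chosen after their values were seen. Coordinates come from matching the listed sequences to miRNA hairpins of GENCODE on GRCm38, not mm39; 59 of the 60 named miRNAs were placed, 4 of them only after end bases were removed. miRNAs between Dlk1 and Dio3 that are not on the list were searched for in the same way after the data were seen.

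Alternatives were RLE, upper quartile and no composition factors, voom with sample quality weights, no filter and a stricter filter, non-robust variances, end variants summed, mouse entries alone, the name series as a covariate, another threshold and a fold minimum, and leaving out each library. Chosen after the data were seen were other prior counts, identical entries counted once, libraries thinned to 2115235 counts, a smooth muscle score as a covariate (the mean log2 CPM of the 4 miR-143 and miR-145 entries) and a fit of all 4 group-by-series cells. The steps were tested on simulated counts with 200 changed miRNAs. Each miRNA was drawn independently, with the spread found within the group-by-series cells. Variation shared between miRNAs and spread between the series were therefore absent, and the shares recovered may not hold for the real libraries. At 4-fold changes 89% were recovered over all 20 placentas, 55% in the F-suffix, 81% in the C/I-infix fit and 48% for the difference between series; at 2-fold changes the shares were 53%, 14%, 42% and 12%. Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 was used for coordinates and plots.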

Results

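miRNAs were profiled in 20 mouse placentas to compare 10 from dams fed freely (control) with 10 from dams on a 50% calorie-restricted diet from embryonic day 8.5 (IUGR). Each group held 5 F-suffix and 5 C/I-infix placentas. Total counts were 6038800 ± 1947800 in control and 3995500 ± 2057900 in IUGR placentas (SD, n = 10 each), a difference of -2043300 (permutation p = 0.0361). The difference was -1623300 in the F-suffix (exact permutation p = 0.230, n = 5 each) and -2463300 in the C/I-infix placentas (exact permutation p = 0.0397, n = 5 each). Nothing in the labels says that the placentas came from separate dams or litters, so all p-values measure the spread between these samples.

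The most abundant miRNAs were miR-143-3p, a smooth muscle and pericyte miRNA, at a mean of 300700 CPM, and miR-21a-5p at 200300 CPM. Behind them were miR-10b-5p at 28330 CPM, let-7f-5p at 22000 CPM and let-7i-5p at 19840 CPM. As library totals were scaled by TMM, these CPM are not shares of all counts. miR-143-3p varied widely and reached 53.3% of all counts in 1 control placenta. Counts in the C/I-infix IUGR placentas varied least, with a median SD of 0.31 on the log2 scale, against 0.83 in the F-suffix IUGR, 0.83 in the C/I-infix control and 1.08 in the F-suffix control placentas (n = 5 each). The first principal component held 63.8% of the variance and did not separate the diets. On it Control 2 (-28.92) lay among the C/I-infix IUGR placentas (-29.94 to -26.38), and IUGR 4 (30.87) lay between Control 10 (27.33) and Control 6 (34.66).

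Across all 20 placentas, caloric restriction went with more miR-5099 and less miR-320-3p. miR-5099 rose from 370 ± 80.9 CPM in control to 738 ± 239 CPM in IUGR placentas (SD, n = 10 each), a 1.93-fold change (log2 0.95, SE 0.20, limma adjusted p = 0.0397), and all 10 IUGR placentas lay above the control median. miR-320-3p, whose hairpin is made without the Drosha step of the usual miRNA pathway, fell from 1040 ± 97.6 to 713 ± 96.8 CPM (log2 -0.55, SE 0.12, limma adjusted p = 0.0397). Its ranges did not overlap, with 873 to 1213 CPM in control and 587 to 845 CPM in IUGR placentas. These were 2 of 694 miRNAs tested, and 224 had an unadjusted p under 0.05, 114 higher and 110 lower. Within the series the log2 change of miR-5099 was 0.63 (SE 0.28) in F-suffix and 1.26 (SE 0.18) in C/I-infix placentas, and that of miR-320-3p was -0.55 (SE 0.22) and -0.56 (SE 0.15). With the name series as a covariate the same 2 miRNAs passed. Neither call held with RLE factors (0 miRNAs), upper quartile factors (0), library size alone (0) or no filter (0). With library size alone miR-320-3p turned to 0.06, but that scaling moved the median of all miRNAs by 0.60. RLE and upper quartile factors moved that median by only 0.028 and -0.167. Leaving out single libraries gave from 0 to 119 miRNAs, the most without IUGR 5, and voom with sample quality weights gave 233 higher and 216 lower.

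The listed miR-5099 sequence did not match the annotated hairpin in full; without its first base, as CTTAGATCGATGTGGTGCTC, it matched on chromosome 12 from 36816249 to 36816268 (GRCm38, plus strand), outside any host gene. miR-320-3p, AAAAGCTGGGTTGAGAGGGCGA, lies on chromosome 14 from 70443557 to 70443578 (plus strand), also outside any host gene.

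**Figure D1:**
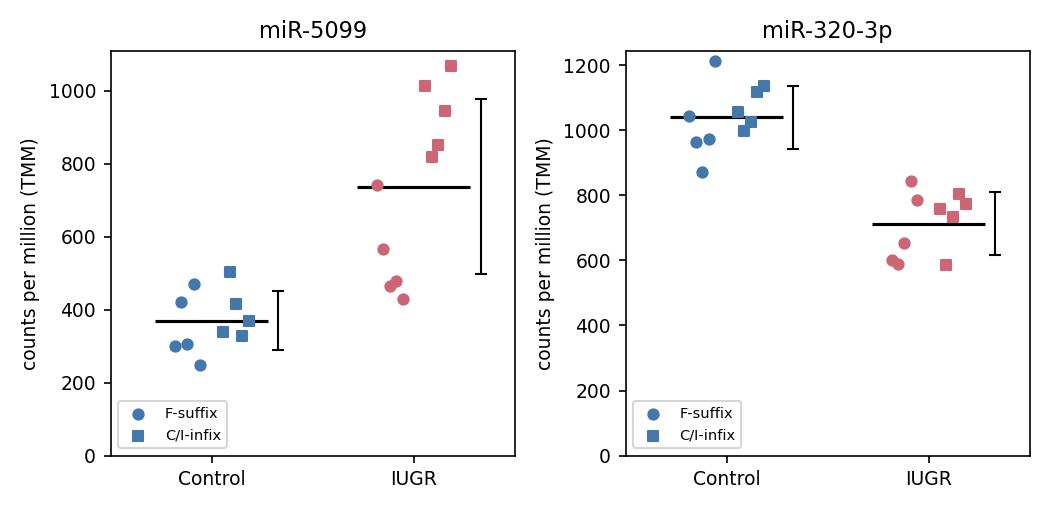
CPM of miR-5099 and miR-320-3p in each of the 20 placentas, by group and name series, with the mean as a line and the SD as a bar. IUGR placentas lie between 587 and 845 CPM for miR-320-3p, all under the 873 to 1213 CPM of the controls. With library size alone as the scaling its log2 change was 0.06, but that scaling moved the median of all miRNAs by 0.60.

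None of the next miRNAs by p passed the test, with adjusted p from 0.0783 to 0.109. Of those with higher values in IUGR placentas, 6 belong to the imprinted Dlk1-Dio3 cluster of chromosome 12. They were miR-496a-3p (log2 1.33, SE 0.34), miR-1197-3p (2.18, SE 0.59), miR-433-5p (1.28, SE 0.38), miR-380-5p (1.35, SE 0.41), miR-376c-3p (1.01, SE 0.32) and miR-758-3p (1.76, SE 0.56). The others were miR-139-5p (0.80, SE 0.21), miR-224-5p (1.03, SE 0.28), miR-30b-3p (0.78, SE 0.21), miR-744-5p (0.40, SE 0.12) and the liver miRNA miR-122-5p (1.35, SE 0.45). With lower values stood 3 miRNAs of the epithelial miR-200 family, miR-200a-3p (-1.91, SE 0.52), miR-200a-5p (-2.18, SE 0.66) and miR-200b-3p (-2.20, SE 0.62), and miR-146a-5p, a regulator of innate immune signalling (-1.01, SE 0.26). Next came miR-31-5p (-1.47, SE 0.41), miR-671-3p (-1.95, SE 0.58), miR-1247-5p (-1.49, SE 0.45), miR-148a-3p (-0.60, SE 0.18), miR-324-3p (-0.59, SE 0.17), miR-425-3p (-0.43, SE 0.13) and miR-107-3p (-0.40, SE 0.12). The miR-107-3p sequence matched 3 loci and is shared with miR-103. With library size alone, which moved the median of all miRNAs by 0.60, the changes of miR-324-3p, miR-148a-3p, miR-425-3p and miR-107-3p turned positive.

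The hypoxia miRNA miR-210-3p did not differ detectably, with 1721 ± 703 CPM in control and 1678 ± 582 CPM in IUGR placentas (SD, n = 10 each; log2 -0.00, SE 0.25, limma adjusted p = 0.996). miR-141-3p, often raised in human growth-restricted placentas, gave 0.01 (SE 0.25), miR-16-5p -0.28 (SE 0.20), miR-29b-3p -0.32 (SE 0.23) and miR-21a-5p -0.77 (SE 0.41). The H19-derived miR-675-3p and miR-675-5p gave 1.05 (SE 0.61) and 1.47 (SE 0.79), and miR-483-3p from an intron of Igf2 gave 1.07 (SE 0.49). Values for miR-322-5p were 1.67 (SE 0.83), for the erythroid miR-451a 0.50 (SE 0.49), for the endothelial miR-126a-3p -0.47 (SE 0.26) and for the myeloid miR-223-3p -1.32 (SE 0.44). None of these passed, and their limma adjusted p ranged from 0.109 to 0.996.

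By list, camera put 5 lists higher and 7 lower in IUGR placentas, of 25 tested. No list passed with an estimated correlation (smallest adjusted p = 0.467, 0 with unadjusted p under 0.05) or with fry (smallest adjusted p = 0.103, 10 with unadjusted p under 0.05). All 79 tested miRNAs on the Dlk1-Dio3 list lay above 0 (median log2 0.74, camera adjusted p = 1.51e-12), and of 5 others placed between Dlk1 and Dio3 but not on the list 3 lay above 0 and 2 below, miR-1247-5p (-1.49) and miR-370-3p (-0.20). Above 0 were also 61 of 62 of the Sfmbt2 cluster families, an imprinted rodent placental cluster (median 1.20, adjusted p = 7.14e-10). The X-linked miR-322/miR-503 cluster (13 of 13 above 0, median 1.58, adjusted p = 8.92e-04), the early embryo and trophoblast cluster miR-290/miR-295 (13 of 13, median 2.71, adjusted p = 6.84e-04) and miR-183/miR-96/miR-182 (6 of 6, median 1.43, adjusted p = 0.0131) were also higher. Lower lists were smooth muscle and pericyte (4 of 4 under 0, median -2.16, adjusted p = 0.0131), fibroblast and stroma (median -1.07, adjusted p = 0.00310), leukocyte (-0.80, 0.0220), epithelial (-1.06, 0.0496), let-7 (-0.33, 0.00127), miR-181 (-0.60, 0.0220) and miR-23/27/24 (-0.40, 0.0456). The medians of let-7 and miR-23/27/24 turned positive with library size alone, which moved the median of all miRNAs by 0.60 on the log2 scale. In the F-suffix placentas camera passed 2 lists and in the C/I-infix placentas 15.

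No member of any list passed the adjustment over all miRNAs. Adjusted over the list alone, 4 of 4 smooth muscle and pericyte, 4 of 7 leukocyte, 5 of 10 epithelial, 4 of 6 striated muscle and 3 of 8 miR-181 miRNAs were lower. So were 2 of 3 liver, 2 of 16 nutrient and lipid, 2 of 13 hypoxia, 1 of 6 miR-29 and 1 of 37 growth-restriction miRNAs. One miRNA each was higher, adjusted over the list alone, in miR-17/92, miR-30, hypoxia, nutrient and lipid, epithelial, miR-183/miR-96/miR-182, striated muscle and liver, and none in the other lists. With the name series as a covariate, 6 of 7 fibroblast and stroma miRNAs were lower by this adjustment, against 0 without it. Epithelial then had 6 of 10 lower, and neuron 1 higher and 1 lower of 7. Lists that camera did not pass over all 20 placentas were miR-17/92 (median 0.41), H19 and Igf2 (1.09), miR-29 (-0.31), miR-30 (-0.16), miR-15/16 (-0.24), miR-34 (0.02), hypoxia (-0.00), nutrient and lipid (-0.26), growth restriction and pre-eclampsia (-0.28), erythroid (0.50), striated muscle (-2.44), liver (-0.96) and neuron (0.28).

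As a share of a library's counts, the smooth muscle and pericyte list held 29.996 ± 17.5% in control and 12.4 ± 14.7% in IUGR placentas (SD, n = 10 each; permutation p = 0.0274, adjusted p = 0.105). The miR-290/miR-295 cluster held 0.996 ± 1.51% and 3.16 ± 2.22% (permutation p = 0.0227, adjusted p = 0.105). Of 26 list shares, 11 had an unadjusted permutation p under 0.05 and 0 passed the adjustment.

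Within the C/I-infix placentas, 4 of 4 smooth muscle, 7 of 7 stroma, 4 of 6 striated muscle and 6 of 10 epithelial miRNAs were lower in IUGR than in control placentas. Higher were 14 of 14 miRNAs of miR-290/miR-295, 13 of 13 of miR-322/miR-503, 56 of 60 of the Sfmbt2 families and 35 of 77 of the Dlk1-Dio3 cluster, and no list passed camera with an estimated correlation (adjusted p = 0.460 or more). The epithelial miR-141-3p was at 0.29 (SE 0.23, limma adjusted p = 0.285). miR-143-3p fell from 479500 ± 300000 to 15270 ± 1501 CPM (SD, n = 5 each; log2 -4.76, SE 0.40, limma adjusted p = 3.09e-05). miR-1a-3p, a muscle miRNA, fell from 4930 ± 2063 to 69.1 ± 26.7 CPM (log2 -6.13, SE 0.40, limma adjusted p = 7.16e-06). Together with these 2, miR-145a-3p (-4.38, SE 0.34), miR-143-5p (-3.99, SE 0.38) and miR-200b-3p (-4.22, SE 0.39) were the 5 decreases with the smallest p among miRNAs with a mean of at least 10 CPM. The increases with the smallest p above the same CPM were those of miR-139-5p (1.25, SE 0.18), miR-5099 (1.26, SE 0.18), miR-380-3p (2.50, SE 0.38), miR-1197-3p (2.75, SE 0.45) and miR-326-3p (1.63, SE 0.27). In all, limma called 356 of 651 miRNAs (54.7%), 200 higher and 156 lower, and 303 of them changed at least 2-fold (log2 of at least 1). In 249 miRNAs (38.2%) the groups did not overlap, against 0.794% by chance. With library size alone 475 were called, 63 of them lower, and the median of all miRNAs moved by 1.07. A fit of all 4 group-by-series cells called 200, or 196 without the 4 entries of the smooth muscle score, and 0 with that score as a covariate. That score did not overlap between the diets here (12.6 to 14.72 in control, 8.941 to 9.647 in IUGR placentas), and its entries were themselves called lower. The 0 therefore cannot tell a tissue share from another cause.

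Of the genomic clusters, 14 of 14 miR-290/miR-295 miRNAs rose within the C/I-infix placentas (median log2 4.55, camera adjusted p = 1.71e-04), such as miR-295-3p from 1185 ± 1539 to 10150 ± 3807 CPM (SD, n = 5 each). No cluster kept its camera call with an estimated correlation (adjusted p = 0.460 or more). All 13 of miR-322/miR-503 rose (median 2.30, adjusted p = 0.00205), including miR-322-5p (3.11, SE 0.88) and miR-503-5p (2.68, SE 0.81). In the Sfmbt2 families 56 of 60 rose (median 2.05, adjusted p = 4.94e-10; 58 adjusted over the list alone), including miR-669c-5p (1.57, SE 0.61), and 35 of 77 rose in the Dlk1-Dio3 cluster (median 0.96, adjusted p = 2.69e-08). The cell-cycle cluster miR-17/92 had 10 of 16 higher (median 0.89, adjusted p = 0.0269), including miR-17-5p (0.95, SE 0.25) and miR-92a-3p (0.89, SE 0.21). All 6 miR-183/miR-96/miR-182 miRNAs rose (median 2.49, adjusted p = 0.0220), including miR-182-5p (2.06, SE 0.63). Of the 4 H19 and Igf2 miRNAs miR-483-3p rose (1.47, SE 0.40), all 4 passed adjusted over the list alone, and camera did not pass the list (adjusted p = 0.113).

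Marker lists fell for smooth muscle and pericyte (4 of 4, median -4.39, camera adjusted p = 2.33e-04) and for fibroblast and stroma (7 of 7, median -1.91, adjusted p = 6.77e-04), with miR-10b-5p at -2.10 (SE 0.33) and miR-199a-5p at -1.79 (SE 0.33). These and the other marker lists also lost their camera calls with an estimated correlation (adjusted p = 0.460 or more). Striated muscle had 4 of 6 lower (median -5.20, adjusted p = 0.00465), including miR-133a-3p (-6.78, SE 0.65), while the heart miRNA miR-499-5p rose (1.32, SE 0.42). The epithelial list had 6 of 10 lower and 2 higher (median -2.01, adjusted p = 0.0289), with miR-200a-3p at -3.50 (SE 0.39) against miR-205-5p (3.49, SE 0.99) and miR-203-3p (1.29, SE 0.48), skin and other stratified epithelium miRNAs. Leukocyte miRNAs fell in 4 of 7 (median -1.33, adjusted p = 0.0220), including miR-223-3p (-2.22, SE 0.34), miR-146a-5p (-1.47, SE 0.24) and miR-150-5p (-1.33, SE 0.37). The leukocyte share of all counts did not fall, at 0.344% in control and 0.355% in IUGR placentas (exact permutation p = 0.794). Camera did not pass liver (2 of 3 lower, miR-192-5p at -2.64 and miR-194-5p, adjusted p = 0.202), neuron (4 of 7 higher, 1 lower, adjusted p = 0.179) or erythroid (miR-144-3p higher at 1.35, SE 0.33, adjusted p = 0.679). The endothelial list had too few members for camera, and its miR-126a-3p fell by 0.73 (SE 0.28, limma adjusted p = 0.0491). That direction turned with library size alone, which moved the median of all miRNAs by 1.07.

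Of the families, let-7 had 10 of 20 lower (median -0.41, camera adjusted p = 0.00796), including let-7c-5p (4685 ± 1735 to 1192 ± 500 CPM, SD, n = 5 each), miR-15/16 had 4 of 10 (-0.49, 0.0220), including miR-195a-5p (-2.67, SE 0.36), miR-23/27/24 had 4 of 9 (-0.53, 0.0410) and miR-181 had 5 of 7 (-0.90, 0.0173). With an estimated correlation 0 of the 25 lists passed (smallest adjusted p = 0.460, 0 with unadjusted p under 0.05), and with fry 22 did. miR-29 had 2 of 6 lower, including miR-29a-3p (-1.80, SE 0.33), and miR-30 had 3 of 11 lower and 1 higher, and camera passed neither (adjusted p = 0.136 and 0.411). All 6 of these family medians turned positive with library size alone, which moved the median of all miRNAs by 1.07. Hypoxia miRNAs went both ways, with miR-21a-5p lower (-1.45, SE 0.22) and miR-322-5p higher (3 higher and 6 lower of 13, camera adjusted p = 0.429), while miR-210-3p was at 0.15 (SE 0.28). Nutrient and lipid miRNAs had 6 of 15 lower, including miR-148a-3p (-0.81, SE 0.20), and miR-375-3p, an islet and endocrine cell miRNA, higher (1.10, SE 0.20; camera adjusted p = 0.133). Growth-restriction and pre-eclampsia miRNAs had 5 higher and 11 lower of 36 (camera adjusted p = 0.160), and the miR-34 family had only miR-34a-5p lower (-0.90, SE 0.25; camera adjusted p = 0.917).

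In shares of all counts, the smooth muscle and pericyte list held 33.8 ± 13.3% of the C/I-infix control and 2.57 ± 0.404% of the C/I-infix IUGR libraries (SD, n = 5 each; exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0129). The miR-290/miR-295 cluster held 0.429 ± 0.596% and 4.31 ± 1.24% (exact permutation p = 0.00794, adjusted p = 0.0129). In 19 of 26 lists the share passed, 14 higher and 5 lower. The let-7 share rose from 8.46 ± 1.87% to 11.5 ± 0.834% (exact permutation p = 0.0159, adjusted p = 0.0229, n = 5 each), opposite in sign to its median above. So did the shares of miR-30 (2.78 to 4.77%), miR-23/27/24 (2.81 to 3.39%), miR-181 (0.166 to 0.193%) and the endothelial list (0.795 to 1.17%), with adjusted p from 0.0129 to 0.0326. Shares of 1 library sum to a fixed total, so others rise where the smooth muscle share drops.

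**Figure D2:**
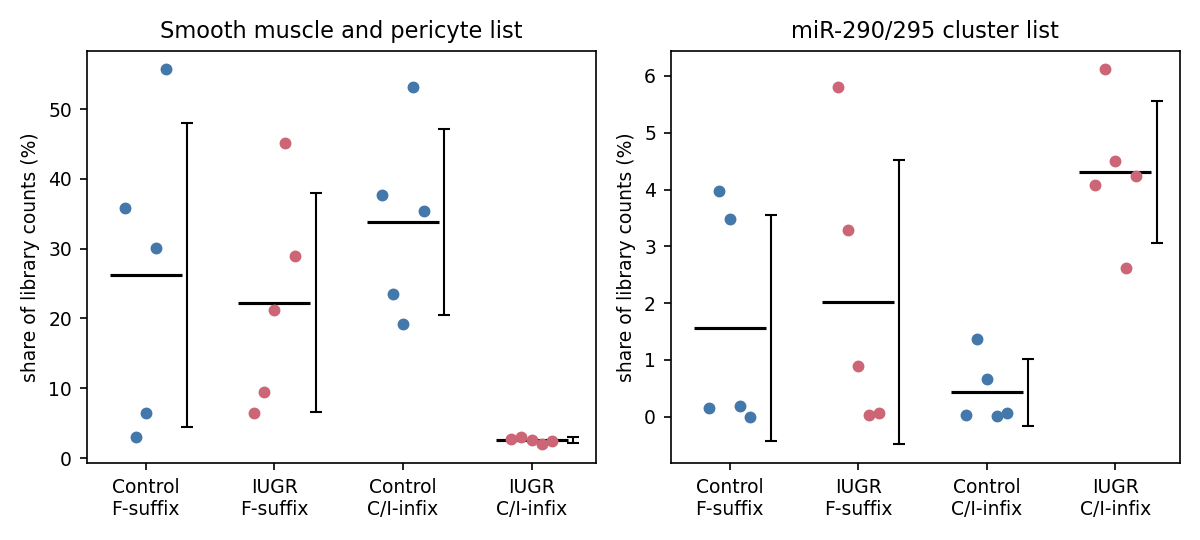
Percent of a library's counts held by the smooth muscle and pericyte list and by the miR-290/miR-295 cluster in each placenta, by group and name series, with the mean as a line and the SD as a bar. The 5 C/I-infix IUGR placentas lie together at 2.57 ± 0.404% for smooth muscle and 4.31 ± 1.24% for miR-290/miR-295, while the F-suffix groups overlap. Control 2, an F-suffix control placenta, lies near them at 3.09% and 3.98%.

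Within the F-suffix placentas, smooth muscle miRNAs did not differ detectably between the diets. miR-143-3p gave a log2 change of -0.04 (SE 1.25) and the smooth muscle and pericyte share was 26.2 ± 21.8% in control and 22.3 ± 15.7% in IUGR placentas (SD, n = 5 each; exact permutation p = 0.754). In Control 2 that share was 3.09%, with 3.98% for miR-290/miR-295, near the values of the C/I-infix IUGR placentas. Such a profile therefore also occurred without the restricted diet. The Dlk1-Dio3 cluster lay above 0 in 77 of 79 miRNAs (median 0.51, camera adjusted p = 4.82e-11) and let-7 below 0 in all but 1 of 22 (median -0.17, adjusted p = 0.00561). With an estimated correlation the smallest adjusted p was 0.869 (0 lists with unadjusted p under 0.05), and fry passed 0 lists (0 unadjusted). The miR-290/miR-295 (0.87), miR-322/miR-503 (0.48), Sfmbt2 (0.33) and striated muscle (0.71) medians were positive and did not pass (adjusted p from 0.215 to 0.258). limma called 0 of 715 miRNAs (smallest adjusted p = 0.997), 12 had an unadjusted p under 0.05, 7 higher and 5 lower, and voom with sample quality weights also called 0. In simulated counts of this fit, with each miRNA drawn independently, 55% of 4-fold and 14% of 2-fold changes were recovered.

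The diet effect itself differed between the series for 27 of 694 miRNAs (limma adjusted p from 0.0305), 26 of them with the lower effect in the C/I-infix placentas. miR-133a-3p (difference of log2 changes, F-suffix minus C/I-infix, 7.49, SE 1.69), miR-1a-3p (6.78, SE 1.57), miR-204-5p (5.05, SE 1.08), miR-200b-3p (4.02, SE 0.87) and miR-200a-5p (4.01, SE 0.91) had the smallest p. In the F-suffix placentas these 5 lay between -0.19 and 0.70. The 1 miRNA with the higher effect in the C/I-infix placentas was miR-2137 (difference -2.37, SE 0.49), which was not placed on the genome. miR-143-3p did not pass (4.70, SE 1.38, limma adjusted p = 0.0618), and miR-320-3p showed no difference of effects (-0.00, SE 0.24). By list, 13 of 25 passed camera, among them striated muscle (median 5.92, adjusted p = 6.72e-04), smooth muscle and pericyte (4.44, 0.00161), fibroblast and stroma (1.81, 0.00161), Sfmbt2 (-1.78, 2.27e-08), miR-290/miR-295 (-3.79, 0.00205) and Dlk1-Dio3 (-0.40, 0.0173). With an estimated correlation 0 passed (smallest adjusted p = 0.456, 2 with unadjusted p under 0.05), and fry passed 3, striated muscle, epithelial and smooth muscle. The count was 16 with library size alone, 86 with voom and sample quality weights, 0 with a smooth muscle score as a covariate, and from 0 to 56 with single libraries left out. Since the score did not overlap between the diets in the C/I-infix placentas, its 0 cannot settle a tissue share.

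**Figure D3:**
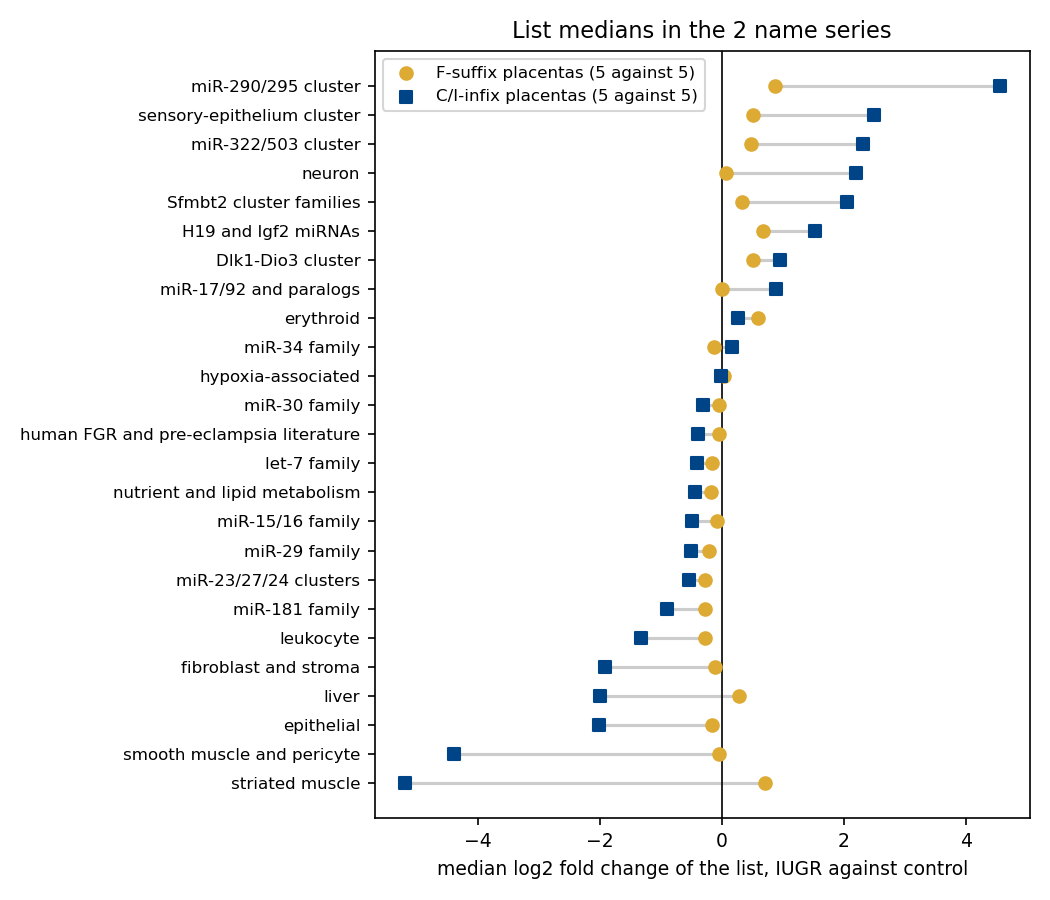
Median log2 fold change of each list, IUGR against control, in the F-suffix and in the C/I-infix placentas. The smooth muscle and pericyte list lies at -0.04 in F-suffix and -4.39 in C/I-infix placentas, and the Dlk1-Dio3 cluster at 0.51 and 0.96. With library size alone the let-7, miR-29, miR-30, miR-15/16, miR-23/27/24 and miR-181 medians of the C/I-infix placentas turn positive. That scaling moved the median of all miRNAs there by 1.07.

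Across miRNAs the log2 changes of the 2 series were related weakly, with Pearson's r = 0.299 and Spearman's rho = 0.369 over 634 miRNAs, which are not independent replicates. Of 347 miRNAs called in the C/I-infix placentas and tested in both, 265 (76.4%) had the same sign in the F-suffix placentas. Between the series themselves, with group as a covariate, limma called 0 of 694 miRNAs (smallest adjusted p = 0.429), 73 had an unadjusted p under 0.05, 41 higher and 32 lower in the F-suffix placentas, and voom with sample quality weights called 164.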

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

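The tests of the same diet effect in both name series, of the Dlk1-Dio3 cluster within each series, of miR-5099 and miR-320-3p within the C/I-infix placentas, of how often other splits gave as much in the F-suffix fit and between the series, and the corrected form of the tissue test for the C/I-infix placentas were chosen or rewritten after their results were seen, and the smooth muscle score was itself added after the data were seen.

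The first pattern is the 356 miRNAs that differed within the C/I-infix placentas, with 27 of 694 miRNAs differing in diet effect between the series. A candidate explanation is a different share of smooth muscle and attached uterine tissue: across 638 miRNAs, the slope on the smooth muscle score within the 5 F-suffix controls, which no IUGR or C/I-infix library entered, gave r = -0.869 with the C/I-infix change (-0.846 from the F-suffix IUGR placentas), and 331 of 345 called miRNAs had the opposite sign. With the 4 entries of the score left out, a fit of all 4 cells called 196 miRNAs without the score and 0 with it. Their median absolute log2 went from 2.39 to 0.58 (median SE 0.63 to 0.61), but lists moved unevenly. Medians kept most of their size for epithelial (-2 to -1.45, calls 6 to 0), liver (-1.99 to -1.66, calls 2 to 0) and an X-linked cluster (-2.81 to -2.36, median SE 0.792 to 1.17). Striated muscle, a list described in advance as one that uterine wall would not bring, went from -5.4 to -1.13. That description was not tested. Among the controls this list rose with smooth muscle (Pearson's r = 0.909, 0.509 without Control 2 and Control 3), so it cannot be used against a tissue share. Most list medians crossed 0, such as miR-290/miR-295 (4.69 to -2.25), Sfmbt2 (2.06 to -1.23), miR-322/miR-503 (2.32 to -1.16) and miR-183/miR-96/miR-182 (2.5 to -1.08). From below, let-7 (-0.497 to 0.316) and fibroblast and stroma (-1.9 to 0.14) crossed too, and neuron grew (0.498 to 1.13). The 0 calls therefore cannot be read as a clean removal of a tissue part. Unequal sequencing depth is argued against by 343 calls with libraries thinned to equal totals. Thinning cannot undo other differences between libraries that may go with low totals, such as PCR copies. An equal diet effect in both series is argued against by a slope of 0.0806 (jackknife SE 0.343, and -0.112 to 0.251 with libraries left out). Without the 3 most abundant miRNAs 348 were called. TMM trims extreme miRNAs in any case, so that count cannot decide on a few dominant miRNAs, and library size alone gave 475 calls. No tissue share was measured, and another factor that moved the same miRNAs would give a similar r. In the C/I-infix placentas the score did not overlap between the diets (12.6 to 14.72 in control, 8.941 to 9.647 in IUGR placentas). The adjusted changes there extend slopes across that gap, so the loss of calls cannot decide. Whether the tissue share differed at all stays open. If it did, the source, be it dissection, litter or the diet itself, which may change the placenta and decidua, is open and untested. The same holds for what lies behind the lists whose medians kept most of their size.

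The second pattern is the Dlk1-Dio3 cluster, with a median above 0 in both series. Its median fell from 0.744 to 0.129 with the smooth muscle score and the name series as covariates, with 53 of 79 miRNAs above 0, and fry's p went from 0.0573 to 0.695, but the score differed between the diets by only 0.006014 in the F-suffix placentas. In a fit of all 4 cells the score took the C/I-infix median from 0.995 to -0.84 (jackknife SE 0.68) and left that of the F-suffix placentas at 0.51 (SE 0.444, 0.508 without the score). A different share of tissue could therefore account for the C/I-infix values, and nothing here shows that it accounts for the F-suffix values, whose spread is too wide to decide. Chance could not be excluded for the median over all 20 placentas, since 8 of 100 splits of the placentas gave a median as large, the highest other 1.031 against 0.744.

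The third pattern is the pair miR-5099 and miR-320-3p. With the score and the name series as covariates at least 70.7% of each log2 change remained, miR-5099 going from 0.95 (SE 0.16) to 0.67 (SE 0.14, limma adjusted p = 0.0458) and miR-320-3p from -0.55 (SE 0.12) to -0.45 (SE 0.11, limma adjusted p = 0.171), which argues against the tissue share as the whole cause but rests on the F-suffix placentas, where the changes were 0.63 and -0.55 and the score hardly differed. Within the C/I-infix placentas the score left 41.3% of the change of miR-320-3p (-0.55, SE 0.17, to -0.23, SE 0.19) and 60.3% of that of miR-5099 (1.27, SE 0.21, to 0.77, SE 0.26), neither passing as folds shrank and errors grew, so the tissue share stays open there. With the score alone neither passed, at 0.60 (SE 0.16, limma adjusted p = 0.217) and -0.48 (SE 0.12, limma adjusted p = 0.166), again with smaller folds. A diet effect on these miRNAs may remain as a hypothesis, and both calls depend on the scaling.

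The first wording of the tissue prediction for the C/I-infix placentas expected a positive r and was wrong, because the score was lower in the C/I-infix IUGR placentas (difference -4.372, against 0.006014 in F-suffix), so the same tissue gives a negative r. Other splits of the samples were counted for each fit. For all 20 placentas, 2 of 100 splits, the real one included, gave at least the real 2 miRNAs, with 51 in the highest other. Few splits reached that count, but a share of 2 in 100, with several fits examined, does not exclude chance. For the C/I-infix placentas only the real split, 1 of 100, gave 356 and the highest other gave 0. For the difference between the series 4 of 100 gave at least 27, which does not exclude chance either, and the highest other gave several times as many. For the F-suffix placentas and for the series themselves the real count was 0, which all 100 of 100 splits must reach, so the count of splits says nothing about chance there. Their highest others, 413 and 165, like those above the real counts of the other fits, point to a structure of the samples besides diet or name.

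The diet effect differed between the series, by the interaction term, for 27 miRNAs, with differences of log2 changes of 7.49 for miR-133a-3p, 6.78 for miR-1a-3p, 5.05 for miR-204-5p, 4.02 for miR-200b-3p, 4.01 for miR-200a-5p and -2.37 for miR-2137. Single samples lay far from the other 9 of their group in 13 of the 176 groups of values examined, where chance gives about 1 in 20. On the log2 CPM scale IUGR 5 had 7.00 for miR-496a-3p (others 8.15 to 9.24), 3.80 for miR-1197-3p (5.70 to 7.56), 4.89 for miR-433-5p (6.32 to 7.18), 4.93 for miR-380-5p (6.38 to 7.30), 5.71 for miR-483-3p (6.88 to 8.23), 0.81 for miR-675-5p (3.20 to 4.91) and 7.81 for miR-141-3p (8.72 to 9.72). It was high for miR-16-5p at 10.86 (9.64 to 10.19) and for miR-34c-5p at 9.39 (7.87 to 8.55). IUGR 4 had 9.01 for miR-322-5p (12.14 to 14.23) and 9.84 for miR-451a (11.29 to 12.64), and IUGR 7 had 3.24 for miR-324-3p (3.91 to 4.60). The epithelial list held 3.53% of the counts of Control 10, against 0.879 to 2.26% in the other controls.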

How the results depend on the processing

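Prior counts, identical entries counted once, thinning, the 4-cell fit and the smooth muscle score were chosen after the data were seen. The 2 miRNAs of the comparison over all 20 placentas became 0 with RLE factors, upper quartile factors, library size alone, no filter and a log2 minimum of 1 (the changes of both are smaller), 37 at an adjusted p of 0.1, 1 of the 2 with libraries thinned, 1 other miRNA and neither of the 2 with the smooth muscle score, and 4.5e+02 with voom and sample quality weights (233 higher and 216 lower), which weighted the C/I-infix IUGR libraries 2.01 to 5.51 against 0.216 to 2.14 for the others. Leaving out 1 library gave 0 to 119, with 119 without IUGR 5, 82 without IUGR 4, 79 without Control 2, 2 without Control 8, 1 without IUGR 3 and 0 without any of the other 15. The F-suffix count stayed at 0 under every setting run, left-out libraries included (0 to 0). The C/I-infix count of 356 stayed within 1.5 times under settings that alter scaling, filter or entries (475 with library size alone, 340 with voom), 257 (without Control 6) to 421 (without Control 8) with 1 library left out, 200 in the 4-cell fit (196 without the entries of the score) and 0 there with the smooth muscle score, where the median fold shrank. The 27 miRNAs that differed between series became 16 with library size alone, 86 with voom and 0 with the score. With 1 library left out they were 0 to 56: 0 without Control 3, 6 or 10 or IUGR 3, 4, 6, 8 or 9, 11 without Control 2, 12 without IUGR 10, 13 without IUGR 2, 15 without Control 4, 16 without IUGR 5, 32 without Control 7, 35 without IUGR 7, 38 without Control 8, 42 without IUGR 1, 51 without Control 1 and 56 without Control 5. Differences between the series themselves went from 0 to 164 with voom and stayed at 0 with any library left out (0 to 0). Lists passing camera went from 12 to 0 with an estimated correlation, 0 with fry and 2 in the F-suffix placentas; list shares passing went from 0 to 19 in the C/I-infix placentas; and the difference in totals was -1623300 in the F-suffix placentas. Beyond what is stated, no cause of these moves was tested.

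Library size alone moved the median of all miRNAs by 0.60, so small negative changes turn by that shift alone. Log2 changes over all 20 placentas turned sign with it for miR-320-3p (0.0569), miR-324-3p (0.00763), miR-148a-3p (0.00960), miR-107-3p (0.20), miR-425-3p (0.17), miR-25-3p (0.43), let-7f-5p (0.38), let-7i-5p (0.46), miR-30a-5p (0.35), miR-16-5p (0.33), miR-27b-3p (0.17), miR-181a-5p (0.24), miR-126a-3p (0.14), miR-210-3p (0.61) and miR-29b-3p (0.29). With the smooth muscle score they turned for miR-669c-5p (-0.00678), miR-25-3p (0.0535), miR-322-5p (-0.10), let-7f-5p (0.0151), miR-27b-3p (0.13), miR-181a-5p (0.0691), miR-21a-5p (0.0658), miR-451a (-0.11), miR-126a-3p (0.10), miR-10b-5p (0.0575), miR-182-5p (-0.0861), miR-1a-3p (0.12), miR-141-3p (-0.44), miR-133a-3p (0.0699) and miR-2137 (-0.10). Upper quartile factors turned miR-34c-5p (-0.10) and miR-141-3p (-0.16), RLE factors miR-210-3p (0.0264), no filter miR-210-3p (0.00376) and mouse entries alone miR-141-3p (-0.0135); none of these changes passed in the main test except miR-320-3p. Of the values of named miRNAs under alternatives, 717 kept direction and side of the threshold, 50 were stronger, 9 weaker and these 35 reversed. The DESeq2 Wald test was not run, since the values were recorded under another unit than counts, nor was a test on values normalized by the authors, since the table held none. No paired analysis was possible because replicate numbers were given in accession order and pair nothing.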

Other observations

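The X-linked miRNA cluster in the first paragraph and the relations among list levels in the next were chosen after values were seen.

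Among the 27 miRNAs whose diet effect differed between the series were 8 of a cluster of miRNAs of the X chromosome known mainly from testis and other reproductive tissue (miR-463, miR-465, miR-470, miR-743, miR-871, miR-881 and relatives). All 14 of its tested miRNAs fell within the C/I-infix placentas (median log2 -2.87), and the direction of the median was the same with every scaling tried, at -2.78 with RLE, -3.06 with upper quartile factors and -1.89 with library size alone, where 5 of the 14 passed. For example miR-881-3p fell from 133.3 ± 80.2 to 22.8 CPM (SD of the controls, n = 5 each; log2 -2.60, SE 0.55, limma adjusted p = 0.00539) and miR-743a-3p from 32.7 to 3.599 CPM (-3.55, SE 0.72, limma adjusted p = 0.00435). In the F-suffix placentas the median was 0.84 and none passed, with miR-881-3p at 0.74 (SE 0.60), and the difference between the series passed for 8 of 18 tested miRNAs of the cluster. The smooth muscle score also differed in the C/I-infix placentas (-4.372). With it as a covariate in a fit of all 4 cells, calls among the 18 went from 16 to 0 within the C/I-infix placentas and from 8 to 0 for the difference, with medians of -2.81 to -2.36 and 3.81 to 3.06 and larger errors (median SE 0.792 to 1.17 and 1.12 to 1.40).

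Among the 10 controls alone, the mean log2 level of the smooth muscle and pericyte list varied together with most other lists, 16 of 24 relations passing (9 positive, 7 negative). It rose with the fibroblast and stroma list (Pearson's r = 0.971, permutation adjusted p = 0.00048; Spearman's rho = 0.976, adjusted p = 0.00144; r = 0.952 without Control 2 and Control 3, the placentas farthest from the median). It fell as the Sfmbt2 families rose (r = -0.855, adjusted p = 0.0042; rho = -0.927, adjusted p = 0.0023; -0.934 without the same placentas) and as the miR-290/miR-295 cluster rose (r = -0.825, adjusted p = 0.00482; rho = -0.952, adjusted p = 0.00176; -0.849). For the Dlk1-Dio3 cluster r was -0.802 (adjusted p = 0.0155; rho = -0.77, adjusted p = 0.0221; -0.792). The relation with striated muscle (r = 0.909, adjusted p = 0.0042; rho = 0.745, adjusted p = 0.0291) was 0.509 without those placentas, as was that with leukocytes (from 0.818), and r fell from 0.893 to 0.583 for let-7, from 0.802 to 0.643 for miR-30 and from 0.837 to 0.679 for miR-181, so these relations, and the count of 16, rest partly on them. No value within a series, of 5 controls each, was computed. List levels are on a log scale relative to the same library total, which by itself sets lists against each other.

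With the smooth muscle score and the name series as covariates, limma passed 2 miRNAs over all 20 placentas, miR-5099 and miR-671-5p, the latter at -2.19 (SE 0.45, adjusted p = 0.0458). With the score alone limma passed only miR-671-5p (-2.32, SE 0.46, adjusted p = 0.0409).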
